A study of Homo sapiens with 2 samples.

How the data were processed

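Total RNA of BT549 cells overexpressing SNHG15 and of BT549 cells with a control vector was sequenced on Illumina libraries, with 1 library per group, per the labels. Whether polyadenylated RNA was selected or ribosomal RNA depleted, whether the libraries kept strand, and which aligner, counter and annotation release were used is not given in the sources used here. The genome build was hg38, per the submitters' processing notes. The library titles spell the overexpressed gene in other ways, and the group was taken from the genotype given in the labels.

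The authors' deposited table held 19029 genes with their Ensembl identifier, symbol and locus. Its counts are whole numbers per gene without normalization, per the file headers and the values deposited. Its FPKM values were deposited by the authors beside the counts, and each equals the count times a factor of the gene and a factor of the library, the latter following the library totals. The deposited log2 ratio equals the log2 of the FPKM ratio of the SNHG15 to the vector library with no pseudocount. The deposited p-values and adjusted p-values come from edgeR, per the name the authors gave the table. The deposited p-values equal those of the edgeR exact test with TMM scaling and an assumed coefficient of variation of 0.1 (largest difference of 4.26e-14 in log10 p). With 1 library per group this variation cannot be estimated, so the deposited p-values rest on that assumption. The deposited subsets of called genes repeat the table of all genes and were not used.

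From the counts, TMM factors were computed with edgeR 4.0.16 in R 4.3.3 (1.04 for the SNHG15 library and 0.960 for the vector library) and CPM values from the scaled totals. The ratio of each gene was given with an exact conditional-binomial (Clopper-Pearson) 95% interval of its 2 counts. Reads are not independent molecules, so these intervals, and floors of 3 counts for a library at 0, cover counting error only. A floor of 3 counts was 0.174 CPM in the SNHG15 library and 0.150 CPM in the vector library. The median gene compared had 284 counts in the SNHG15 library and 315 in the vector library. Log2 ratios used a prior count of 2.

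Genes with a mean of at least 1 CPM were compared, 12934 in number, of which 11568 were protein-coding. A gene was beyond 2-fold where its whole interval lay above 2 or below 0.5. The median log2 ratio of each of 43 gene lists was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Named genes were SNHG15, the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 CPM by the interval bound nearest to 1, up to 4 members of each list that stood apart and of each cell type or RNA quality list, up to 2 members of other lists, the measured neighbours of SNHG15, and the 5 most abundant genes of each library. CDH2, MX2, FOXM1 and MALAT1 were named in addition after their values were seen, as members that went against their list. BCYRN1, DHRS3, RARRES1, TGM2, RARB, STRA6, HOXB2, RBP4, MEIS2, CRABP2, SENP3-EIF4A1 and AC092143.1 were also chosen after their values were seen. Some genes that the rule names are not reported here. The groups, the 43 gene lists, the main tests, the naming rule and the first set of alternatives were chosen before the data were examined. A list of retinoid pathway genes, described among the other observations, was added later.

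Biotype, exonic length and transcript GC content came from GENCODE 29 on GRCh38, which matched 18903 identifiers, 17742 of them at the same locus. GC and length trends were removed by loess with a span of 0.5 over the genes that had a value (99.7% for GC). Of the genes compared, 15.7% overlapped another gene of the table on the same strand, against 20.8% of those beyond 2-fold. Reads of overlapping genes, antisense pairs and near-identical paralogs may be divided among them, and their values are uncertain. Besides the readthrough genes, this holds among the genes named for TGIF2, SSTR2, PAK6, IFITM1, CDH11, MMP2, AKR1C1, CD68, MAGEA12, CANX, HERPUD1, H2BC21, RN7SL2 and MT-ND4, which overlap a gene of the same strand. Other named genes overlap a gene of the opposite strand, among them CEMIP, THBS2, PRKCZ, ADIRF, LIF, KIF20A and CDC25C. Their values are uncertain too, since it is not known whether the libraries kept strand.

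Alternatives were DESeq2 1.42.0 size factors, library totals, no filter and a minimum of 5 CPM, random thinning of the deeper library, removal of GC or length trends, point ratios, FPKM with pseudocounts of 1 and 0.1, protein-coding genes only, prior counts of 0.5 and 10, unmatched random lists and means of members. Alternatives added later were genes without same-strand overlap, window centring and the authors' test at other assumed variations. Window centring subtracted the median of windows of at least 40 neighbouring genes after removal of the GC trend. The functions were tested on simulated data with 200 changed genes among 12924. The rule recovered 85.0% of genes changed 3-fold and 99.0% of those changed 5-fold, and called 0 unchanged genes when counting error was the sole error. It recovered 0% of genes changed 1.5-fold, which follows from its limit of 2-fold and does not measure sensitivity. Of 200 simulated lists of 20 genes with independent values and no shift, 8 stood apart. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.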

Results

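RNA was profiled by sequencing in BT549, an established human breast cancer cell line of mesenchymal character that lacks the oestrogen and progesterone receptors. Cells overexpressing SNHG15, a long non-coding RNA gene that hosts a small nucleolar RNA, were compared with cells carrying a control vector. Each group held 1 library, so no difference below has a replicate check, no p-value was computed across libraries, and the 95% intervals cover counting error only. The SNHG15 library held 16570496 counts over 18086 genes with at least 1 count, and the vector library held 20799017 counts over 18144 genes. The 10 most abundant genes took 7.78% of the counts in the SNHG15 library and 7.93% in the vector library.

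The comparison asked which genes differ in level when SNHG15 is overexpressed. SNHG15 (ENSG00000232956), a long intergenic non-coding RNA gene on the minus strand of chromosome 7 at 44983023 to 44986961 (hg38), was at a scaled count (CPM) of 1997 in the SNHG15 library and 23.3 CPM in the vector library, an 85.6-fold difference (95% interval 78.1 to 94.0, from 34450 and 466 counts). The median ratio of 23 interferon-stimulated genes (11 higher, 1 lower) and of 40 genes of mitosis (13 higher, 1 lower) lay above that of matched random lists. The median lay below it for 13 inflammatory cytokines (0 higher, 12 lower), 20 mesenchymal markers (3 higher, 9 lower), 21 matrix proteases and regulators (0 higher, 9 lower), 13 genes of MHC class I presentation (0 higher, 6 lower), the 13 mitochondrially encoded messages (0 higher, 7 lower) and 6 abundant structural RNAs (1 higher, 4 lower). Collagens and other matrix genes moved in both directions, with the thrombospondin THBS2 9.14-fold higher (8.17 to 10.2) and the type I collagen chain COL1A2 7.33-fold lower (6.81 to 7.89). The counts do not separate SNHG15 transcripts of the vector from those of the genome.

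Of 12934 genes with a mean of at least 1 CPM, 285 were beyond 2-fold higher and 317 beyond 2-fold lower in the SNHG15 library, meaning that the whole 95% interval of the ratio lay past 2-fold. Together these 602 genes made up 4.65% of the genes compared. The split depended on the scaling, since scaling by library totals in place of TMM raised the median log2 ratio of all genes by 0.12 and gave 363 higher and 237 lower. On unchanged genes simulated with a coefficient of variation of 0.2 added to counting error, the same rule called 54 of 12924 genes, and with 0.4 it called 1756.

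**Figure D1:**
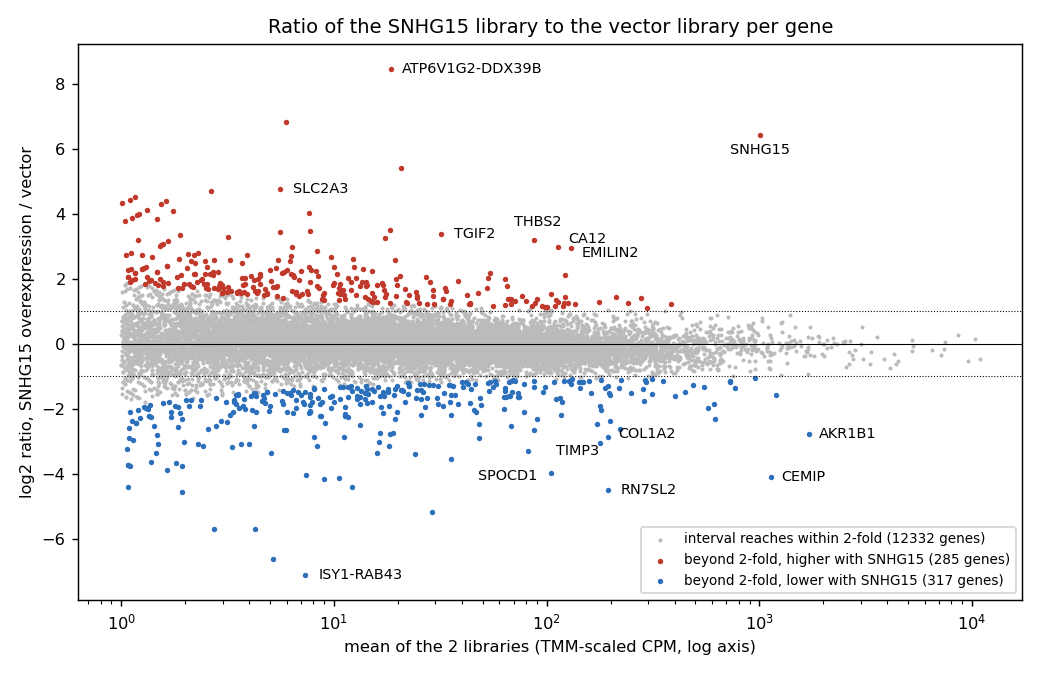
Log2 ratio of the SNHG15 library to the vector library (vertical axis) against the mean TMM-scaled CPM of both libraries (log axis) for the 12934 genes with a mean of at least 1 CPM, 1 point per gene. Red points mark the 285 genes beyond 2-fold higher and blue points the 317 beyond 2-fold lower; SNHG15 lies among the abundant genes at a log2 ratio of 6.41.

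Among protein-coding genes with a mean of at least 5 CPM, the genes highest in the SNHG15 library by the interval bound nearest to 1 had varied functions. SLC2A3, the glucose transporter GLUT3, was 36.1-fold higher (16.3 to 99.6), at 187 counts against 6. The somatostatin receptor SSTR2 was 18.1-fold higher (10.9 to 32.1). PRSS12, a secreted serine protease, was 11.6-fold higher (8.87 to 15.5) and TGIF2, a homeobox repressor of TGF-beta signalling, 10.6-fold higher, at 58.4 CPM against 5.51, with the caution that TGIF2 and SSTR2 overlap other genes of the same strand. The kinase PRKCZ was 11.9-fold higher, the tyrosine catabolism enzyme HPD 12.1-fold, the membrane skeleton protein ADD2 9.89-fold and the transcription factor SOX3 8.45-fold. CA12, a membrane carbonic anhydrase, rested on deeper counts and was 7.89-fold higher (7.18 to 8.68), at 199.8 CPM against 25.3. EMILIN2, a matrix glycoprotein of elastic fibres, was 7.68-fold higher (7.05 to 8.38).

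On the lower side, CEMIP, a hyaluronan-degrading protein, went from 2137 CPM in the vector library to 125.8 CPM in the SNHG15 library, 17.0-fold lower (16.3 to 17.8). AKR1B1, the aldose reductase, was 6.84-fold lower, at 435.7 CPM against 2979 (59504 counts in the vector library). TIMP3, an inhibitor of matrix metalloproteinases, was 8.35-fold lower (7.70 to 9.06). The junction protein and lipoprotein receptor LSR was 23.6-fold lower (14.6 to 40.8), the kinase PAK6 19.2-fold, SPOCD1 15.7-fold, the zinc-finger protein ZNF488 11.8-fold and ADIRF 10.6-fold. Of these, PAK6 overlaps another gene of the same strand, so its reads may be divided. The same ranking also held readthrough genes, whose models span neighbouring genes, so that reads may be divided among them. ATP6V1G2-DDX39B had 641 counts against 0 and was at least 247-fold higher against a floor of 3 counts in the vector library (200.6-fold by the lower bound of the exact interval). ISY1-RAB43 had 0 counts against 293 and was at least 84.4-fold lower by the same floor in the SNHG15 library (68.2-fold by the exact interval). ATP5MF-PTCD1 was 39.0-fold lower (26.3 to 60.6) and ARPIN-AP3S2 10.7-fold lower. For each of these 4 readthrough genes, the counts pooled with those of the overlapping genes lay within 2-fold, with pooled ratios of 1.01, 1.28, 0.711 and 1.33. Pooling could not have shown a 2-fold difference here and decides nothing about the cause. With the rest of each locus equal in both libraries, the pooled ratios would have been 1.135, 0.732, 0.849 and 0.626.

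Gene lists fixed beforehand were described by the median log2 ratio of their measured members. A member was counted as higher or lower where its interval excluded 1 and its ratio reached 1.5-fold. A list stood apart where its median fell outside the central 95% of 10000 random lists matched on mean expression. Of 38 lists with at least 5 measured members, 12 stood apart, 6 on each side, against 1.90 expected of lists of independent genes. Genes of a list can vary together between any 2 cultures, and some lists share genes. The 12 against 1.90 therefore does not measure an excess over chance. Ratios also followed transcript GC content across genes (Spearman's rho −0.32 over 12895 genes, which are not independent replicates), so medians with this trend removed are given beside each list that stood apart and where they change the call of another.

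Interferon-stimulated genes had a median log2 ratio of 0.55 over 23 measured members (percentile 99.96; 0.63 with the GC trend removed). In this list 11 genes were higher, 1 was lower and 11 were neither. OASL, an oligoadenylate synthetase-like antiviral protein, was 6.25-fold higher (4.22 to 9.56), the membrane antiviral protein IFITM1 4.99-fold (3.67 to 6.88), the ISG15 ligase HERC5 7.33-fold (3.60 to 16.9) and tetherin, BST2, 3.91-fold (2.20 to 7.31). All 4 were expressed at low levels, with 30, 52, 9 and 16 counts in the vector library. MX2, another antiviral effector, was the lower member, at 20 counts against 145.

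Genes of MHC class I presentation had a median of −0.36 (13 measured; percentile 2.31; −0.38 with the GC trend removed), with 0 higher, 6 lower and 7 neither. HLA-B was 2.77-fold lower (2.54 to 3.04), NLRC5, the transactivator of class I genes, was 1.91-fold lower (1.64 to 2.22) and HLA-C 1.74-fold lower (1.67 to 1.81). The HLA genes share sequence, so the division of reads among them is uncertain. Inflammatory cytokines and chemokines had a median of −0.93 (13 measured; percentile 0.0; −1.03 with the GC trend removed), and 12 of the 13 were lower with 0 higher. IL1B was 3.17-fold lower (2.71 to 3.73) and the neutrophil chemokines CXCL3 and CXCL8 2.46-fold (2.11 to 2.87) and 2.29-fold (1.97 to 2.66). LIF, a cytokine of the IL-6 family, was at 98.8 CPM against 296.7 (ratio 0.333, 0.315 to 0.352).

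Mesenchymal markers had a median of −0.51 (20 measured; percentile 0.01; −0.44 with the GC trend removed and −0.33 with window centring), with 3 higher, 9 lower and 8 neither. The cadherin CDH11 was 2.43-fold lower (2.15 to 2.76), fibronectin, FN1, 1.80-fold (1.76 to 1.84) and the gelatinase MMP2 1.79-fold (1.73 to 1.86). The surface glycoprotein THY1 was at 502.7 CPM against 1007 (ratio 0.499, 0.487 to 0.512). CDH2, N-cadherin, went the other way and was 5.28-fold higher (4.13 to 6.82), and with the mean of members in place of the median (−0.18) the list no longer stood apart. Matrix proteases and their regulators had a median of −0.49 (21 measured; percentile 0.02; −0.60 with the GC trend removed), with 0 higher, 9 lower and 12 neither. Besides TIMP3 and MMP2, the urokinase PLAU was 1.98-fold lower (1.90 to 2.06) and its inhibitor SERPINE2 1.83-fold lower (1.76 to 1.90). Collagens and matrix genes had a median of 0.26 (28 measured; percentile 99.97; 0.44 with the GC trend removed), with 8 higher, 7 lower and 13 neither. Besides THBS2, tenascin C, TNC, was 2.69-fold higher (2.56 to 2.82) and biglycan, BGN, 3.29-fold (2.32 to 4.75). The basement membrane collagen COL4A1 was at 114.9 CPM against 45.9. The matrix list did not stand apart by its mean (0.09) or with no filter on low counts (median 0.10).

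Genes of the G2/M phase and mitosis had a median of 0.43 (40 measured; percentile 100.0; 0.27 with the GC trend removed and 0.21 with window centring), with 13 higher, 1 lower and 26 neither. The mitotic kinesin KIF20A was 2.03-fold higher (1.90 to 2.17), the phosphatase CDC25C 2.07-fold (1.79 to 2.39), the kinetochore protein CENPF 1.89-fold (1.60 to 2.24) and cyclin B1, CCNB1, 1.61-fold (1.52 to 1.71). KIF20A and CDC25C lie close together on chromosome 5. Their stretch, from 71587288 on, had a median of 0.31 over 415 genes with the GC trend removed. The lower member was FOXM1, a transcription factor of mitotic genes, with a log2 ratio of −1.11. Genes of the G1/S transition and DNA replication had a median of 0.06 and did not stand apart (38 measured, 4 higher, 1 lower), but did with window centring (0.12). Hypoxia and glycolysis genes had a median of 0.19 (35 measured; percentile 99.66; 0.19 with the GC trend removed and 0.30 by library totals), with 5 higher, 3 lower and 27 neither. Besides SLC2A3 and CA12, the glucose transporter SLC2A1 was 2.59-fold higher (2.41 to 2.80). The mTORC1 inhibitor DDIT4 was 1.42-fold higher (1.39 to 1.44), short of 1.5-fold and so counted as neither. This list did not stand apart against random lists without matching on expression, or when ratios were centred on windows of neighbouring genes (median 0.10).

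Ribosomal protein genes had a median of 0.10 (70 measured; percentile 100.0; 0.06 by DESeq2 size factors and 0.22 by library totals), with 3 higher, 3 lower and 64 neither, and did not stand apart with the GC trend removed (0.06), with window centring or against unmatched random lists. RPS16 was 1.74-fold higher (1.71 to 1.78) and RPS6 1.56-fold (1.53 to 1.59). The 13 protein genes of the mitochondrial genome had a median of −0.59 (percentile 0.0; −0.73 with the GC trend removed), with 0 higher, 7 lower and 6 neither. The complex I subunit genes MT-ND3 and MT-ND4 were 2.25-fold (2.19 to 2.31) and 1.67-fold (1.65 to 1.69) lower. Genes of the mitochondrial genome took 3.71% of the counts in the SNHG15 library and 4.87% in the vector library. Nuclear genes of oxidative phosphorylation had a median of −0.17 and did not stand apart (40 measured, 0 higher, 6 lower), but did on the lower side with the GC trend removed (−0.25) and with window centring (−0.22).

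Among abundant structural RNAs the median was −1.76 (6 measured; percentile 0.0; −1.47 with the GC trend removed), with 1 higher, 4 lower and 1 neither. The signal recognition particle RNAs RN7SL2 and RN7SL1, near-identical copies between which reads can be divided, were 22.9-fold (20.3 to 25.9) and 9.82-fold (8.65 to 11.2) lower. RMRP was 3.73-fold lower (2.76 to 5.13) and RPPH1, the RNA of ribonuclease P, 3.23-fold lower (2.47 to 4.28), while the long non-coding RNA MALAT1 was 1.90-fold higher. Replication-dependent histone genes had a median of 0.46 (8 measured; percentile 97.57; 0.66 with the GC trend removed), with 3 higher, 0 lower and 5 neither. The histone genes H2BC21 and H4C8 were 2.57-fold (2.06 to 3.22) and 2.21-fold (1.42 to 3.50) higher. The histone list was lost without the filter on low counts and with a minimum of 5 CPM, and with a prior count of 0.5.

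Among the other small nucleolar RNA host genes, GAS5 was 2.17-fold higher (2.02 to 2.32), and the family including SNHG15 had a median of 0.15 (22 measured, 2 higher, 2 lower, percentile 89.72). By its mean, which SNHG15 itself raises, the family stood apart (0.36). The measured neighbours of SNHG15 had a median of −0.41 (7 measured, 0 higher, 3 lower, percentile 4.48), which was −0.27 with the GC trend removed and −0.06 with window centring in addition. Of these, TBRG4 was 1.83-fold lower (1.75 to 1.91), CCM2 1.72-fold (1.60 to 1.85) and ZMIZ2 1.54-fold (1.45 to 1.64). OGDH was 1.33-fold lower (1.28 to 1.37), short of 1.5-fold and so not counted as lower. For PURB, H2AZ2 and PPIA the intervals of the ratio included 1 (0.937 to 1.23, 0.919 to 1.05 and 0.993 to 1.04).

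Few markers of other cell types were measured. Luminal breast markers had a median of −0.40 (8 measured, 2 higher, 2 lower, percentile 3.93), and stood apart with window centring (−0.32) and against unmatched random lists, with keratin KRT18 1.71-fold lower (1.67 to 1.75). Basal breast markers had a median of −0.08 (8 measured, 1 higher, 3 lower) that was 0.04 by library totals, with KRT14 9.32-fold lower (6.32 to 14.3) at 28 counts against 302. Epithelial markers had a median of −0.48 (5 measured, 0 higher, 2 lower, percentile 5.56), and stood apart with the GC trend removed (−0.65), with window centring (−0.80) and by their mean (−0.94), with the claudin CLDN7 at 2 counts against 40, a ratio of 0.0579 (0.00678 to 0.223). Of haematopoietic and endothelial markers 3 each were measured, with CD68 4.92-fold lower (3.79 to 6.46) and the receptor TEK at 3 counts against 74, a ratio of 0.0469 (0.00946 to 0.143). Neural markers had a median of −0.08 (6 measured, 1 higher, 2 lower; 0.03 by library totals), and 0 of 14 hepatocyte markers reached a mean of 1 CPM. All 4 measured cancer-testis genes were lower, among them PRAME at 3.07-fold (2.79 to 3.37). The other 3, MAGEA6, MAGEA12 and MAGEA3, are close paralogs.

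**Figure D2:**
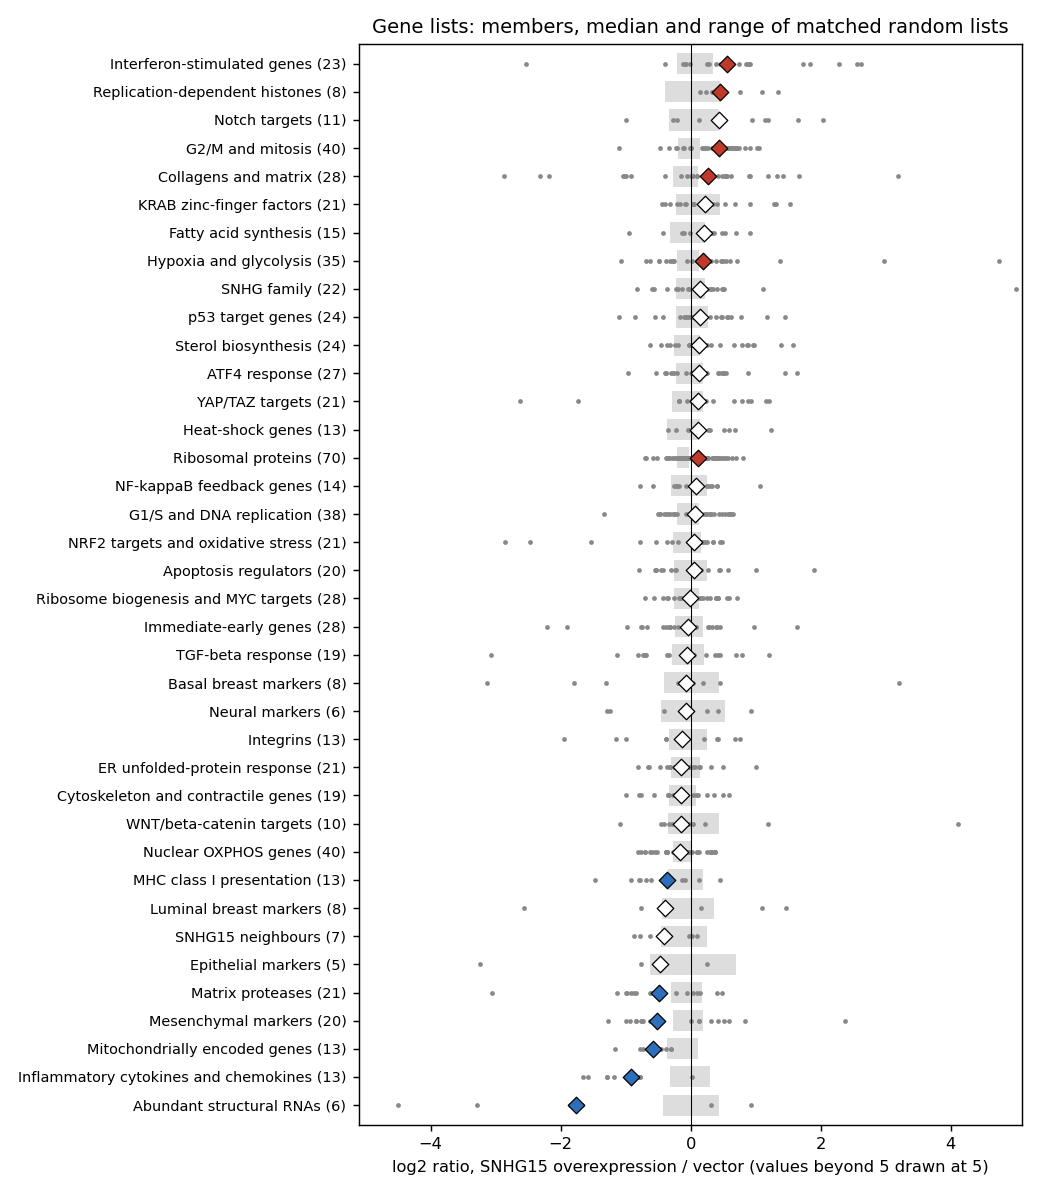
Log2 ratios of the SNHG15 library to the vector library for the 38 gene lists with at least 5 measured members (number in parentheses). Small grey points are members, diamonds are list medians and grey bars span the central 95% of 10000 matched random lists; red and blue diamonds mark the 6 higher and 6 lower lists that stood apart, from 0.55 for interferon-stimulated genes to −1.76 for structural RNAs.

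Ratios also differed by chromosome. With the GC trend removed, the median log2 ratio was −0.26 for chromosome 7 (600 genes) and −0.24 for chromosome 20 (361 genes). For chromosomes 22 (341 genes) and 11 (718 genes) it was −0.20. It was 0.26 for the 439 genes of chromosome 14 and 0.24 for the 583 genes of chromosome 5. Medians of 16 of the 23 chromosomes lay outside the range of 1000 shuffles of gene positions. SNHG15 and the neighbours named above lie on chromosome 7, where 75.5% of genes had a log2 ratio below 0 with the GC trend removed.

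**Figure D3:**
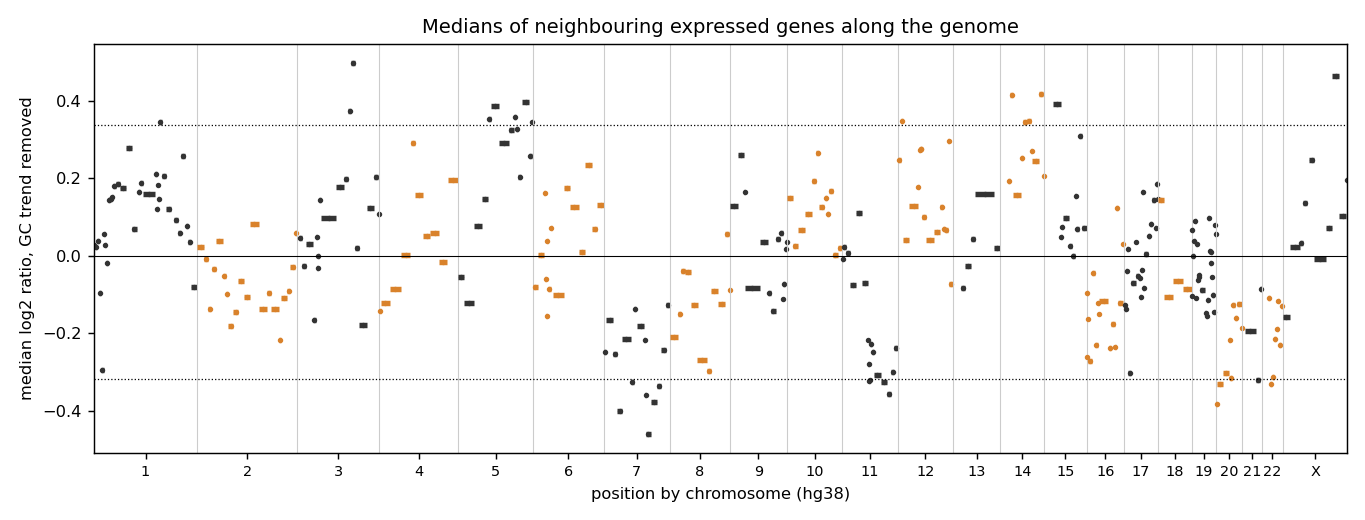
Median log2 ratio of the SNHG15 library to the vector library, with the GC trend removed, against position in hg38. Each of 310 windows held at least 40 neighbouring expressed genes. Bars are drawn to the extent of each window, with dots at its middle and colours alternating by chromosome. The lowest window of a shuffle fell below the dotted line at −0.32, and the highest rose above that at 0.34, in 2.5% of shuffles each, and 29 windows lie outside these lines, among them windows of chromosomes 5, 7, 11 and 14.

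In the authors' deposited table, 1551 genes were called different, 929 higher and 622 lower. The thresholds were an absolute log2 ratio of FPKM of at least 1 and an adjusted p-value below 0.05. FPKM follows the library totals, and by TMM scaling 1409 of the 1551 reached 2-fold in the same direction. The authors' deposited table shared 597 of the 602 genes beyond 2-fold described here, which come from the same counts. Of the calls in the authors' deposited table, 303 had a mean under 1 CPM and 129 had an infinite log2 ratio because 1 library had 0 counts.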

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

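The tests with overlap-free genes, window centring and other assumed variations were chosen only after the result was seen. SNHG15 was 83.2-fold higher by DESeq2 size factors and 92.8-fold by library totals and by FPKM. Counts of genes beyond 2-fold stayed within 1.5 times of 285 higher and 317 lower, except that a mean of at least 5 CPM gave 162 higher from fewer genes, point ratios gave 703 higher and 631 lower, and FPKM with a pseudocount of 1 gave 144 and 153. With an assumed coefficient of variation of 0.2 in place of 0.1, the authors' test gave 598 calls, and with 0.4 it gave 26. From 12 to 17 lists stood apart under the alternatives. Of 501 list values, 433 kept their direction and side of the threshold, 11 stood apart no longer, 30 newly stood apart, and 26 changed sign without standing apart under either setting. The NRF2 targets reversed by the mean of members (−0.30), where they stood apart. Of 438 values of 146 named genes, 427 kept their direction and whether the interval excluded 1, 3 lost and 3 gained that, and 3 changed sign with intervals that included 1. FLNA (0.12) and PPIA (−0.11) reversed with the GC trend removed. For these reversals the cause was not tested. Genes near 1 CPM have about 20 counts and can show large ratios alone. No paired analysis was possible because each group has 1 library, and no library could be left out.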

Other observations

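The tests of GC content, copy number and histone genes were chosen only after the result was seen, as were the genome segments named and the corrections of the retinoid genes. Several gene groups outside those that stood apart held members with large differences. Notch pathway genes had a median log2 ratio of 0.43 (11 measured, 5 higher, 1 lower, percentile 97.39), with the ligand DLL1 4.15-fold higher (3.31 to 5.24) and the target HES4 3.18-fold (2.54 to 4.01). Sterol biosynthesis genes had a median of 0.13 (24 measured, 8 higher, 1 lower, percentile 97.23). With the GC trend removed both lists stood apart, at 0.67 and 0.22, and in all the Notch list did under 8 and the sterol list under 5 of 12 alternatives. Fatty acid synthesis genes (median 0.20, 15 measured, 2 higher, 1 lower) held SCD at 1.63-fold higher and ACSS2 at 1.94-fold lower. Among NRF2 targets (median 0.05, 21 measured, 0 higher, 4 lower), the aldo-keto reductases AKR1C1 and AKR1C2, paralogs that may share reads, were 5.56-fold (4.87 to 6.38) and 7.53-fold lower. Among immediate-early genes (median −0.04, or 0.08 by library totals, 28 measured, 2 higher, 6 lower), IER2 was 4.64-fold (4.01 to 5.38) and the AP-1 member FOSL1 3.76-fold (3.54 to 3.99) lower.

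Among p53 targets (median 0.15, 24 measured, 4 higher, 2 lower), the cell cycle inhibitor CDKN1A was 2.72-fold higher (2.55 to 2.90) and GDF15 2.15-fold lower (1.93 to 2.40). Of apoptosis regulators (median 0.05, 20 measured, 2 higher, 1 lower), BCL2L11, which encodes BIM, was 3.80-fold higher (2.86 to 5.11). Heat-shock genes (median 0.11, 13 measured, 3 higher, 0 lower) held HSP90AA1 at 2.35-fold higher (2.26 to 2.43). In the ATF4 response (median 0.13, 27 measured, 3 higher, 1 lower) NUPR1 and ATF3 were 2.74-fold and 3.25-fold higher, and in the unfolded-protein response (median −0.15, 21 measured, 1 higher, 3 lower) CANX was 2.02-fold higher and HERPUD1 1.75-fold lower. Of integrins (median −0.13, 13 measured, 2 higher, 3 lower), the fibronectin receptor chain ITGA5 was 2.22-fold (2.16 to 2.28) and ITGA11 3.87-fold (3.30 to 4.55) lower. In the TGF-beta response (median −0.06, or 0.06 by library totals, 19 measured, 3 higher, 7 lower), INHBA was 10.4-fold lower at 7 counts against 84 and TGFB3 2.33-fold higher. Of YAP/TAZ targets (median 0.11, 21 measured, 6 higher, 2 lower), the lower members DLC1 and FOXF2 were 7.07-fold and 3.55-fold lower. Of WNT targets (median −0.16, 10 measured, 2 higher, 1 lower), NKD2 had 45 counts against 1, a ratio of 52.1 (8.89 to 2103), and AXIN2 was 2.34-fold higher. NF-kappaB feedback genes (0.08) did not stand apart, but did with the GC trend removed (0.25) and with a minimum of 5 CPM (0.25). Heat-shock genes did with the length trend removed (0.17), by their mean (0.25) and with window centring (0.22), and fatty acid synthesis genes with window centring (0.31). Ribosome biogenesis genes (−0.01, or 0.11 by library totals), KRAB zinc-finger genes (0.22), cytoskeletal genes (−0.15) and the 4 measured metallothioneins (−0.41) did not stand apart, except the metallothioneins with no filter on low counts (−0.73, 5 measured).

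Ratios shifted together along long stretches of chromosomes, a pattern found and tested on the same data. On chromosome 5 the median log2 ratio with the GC trend removed was 0.01 over 168 genes up to 71567820 and 0.31 over 415 genes from 71587288, and on chromosome 11 it was −0.01 over 256 genes up to 60952530 and −0.29 over 462 genes from 61130256. The GC trend was not the whole cause, because the SD of the chromosome medians was still 0.149 after its removal, against at most 0.0424 with shuffled positions, nor were low counts, because it was 0.156 among 5921 genes with a mean of at least 20 CPM, against at most 0.0553 with their positions shuffled. A different chromosome copy number between the cell populations stays open as a hypothesis, since the correlation of adjacent windows, 0.735 against at most 0.166 with shuffled positions, restates the pattern and would follow from any regional cause. With 1 library per group, an effect of SNHG15 itself cannot be told apart from a difference between the cell populations.

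Of the genes beyond 2-fold, 14 were readthrough genes, and 0 of the 14 were beyond 2-fold once pooled with the same-strand genes they overlap. This does not decide whether reads were divided differently among overlapping gene models, because with the rest of the locus equal in both libraries the pooled ratio would have passed 2-fold in 0 of the 14. At the locus where the readthrough gene held most of the vector counts, SENP3-EIF4A1, the pooled ratio was 0.963, with the readthrough gene at a ratio of 0.180 and the remaining genes at 2.15. The closest to 2-fold was AC092143.1, which spans MC1R and TUBB3, with a pooled ratio of 1.98 (1.91 to 2.05). A division of reads and a change in readthrough transcription cannot be told apart from these counts.

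The RNAs RN7SL1, RN7SL2, RMRP and RPPH1, all transcribed by RNA polymerase III, were lower in the SNHG15 library, and so was BCYRN1, another such RNA, at 9 counts against 41. A lower recovery of short RNA was argued against as the whole cause by 165 other genes of at most 500 nt. This set left out 7SL copies and mitochondrial genes, and its median log2 ratio was −0.0646 (percentile 3.67 of matched random lists). That was far less than the log2 ratios of RN7SL2 (−4.51), RN7SL1 (−3.29), RMRP (−1.86) and RPPH1 (−1.665). With the 3 mitochondrial messages of that length the median was −0.09 (percentile 1.61). Across genes the ratio also rose weakly with exonic length (Spearman's rho 0.13). A weak trend with length was therefore present, and a small effect of length on these RNAs is not excluded. The set was chosen by annotated exonic length, and its reads were not checked to come from short transcripts, which limits this test. A lower recovery of RNA without a poly(A) tail cannot be told apart from lower levels in the cells. Replication-dependent histone genes had a median of 0.456, but 3 of the 8 measured had a mean of at least 20 CPM, and some histone genes also give polyadenylated transcripts. A lower polymerase III output was not tested.

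The retinoid-linked genes DHRS3, RARRES1 and TGM2 were among those beyond 2-fold lower, with log2 ratios of −2.31, −2.89 and −1.98. A lower activity of retinoic acid receptors was taken to lower other genes of the pathway. These came from a list of 32 retinoid pathway symbols, added after the 3 genes were seen. That list was not among the 43 lists fixed beforehand. The 21 other genes measured had a median of −0.32 (percentile 1.21 of matched random lists). Members went both ways, but more of them were lower than higher, and those named here are examples of each direction. The receptor RARB was 2.43-fold (1.94 to 3.06), STRA6 1.74-fold and HOXB2 1.38-fold lower. The retinol binding protein RBP4 was 2.34-fold (2.04 to 2.68), MEIS2 1.55-fold and CRABP2 1.465-fold higher. The 21 also include other receptors and enzymes of retinol metabolism, which such activity need not lower. With the GC trend removed the median was −0.19 (percentile 5.05), and with window centring in addition −0.23 (percentile 1.06), so the result depends on the correction and the hypothesis stays open.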
